A study of Homo sapiens with 12 samples.

How the data were processed

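RNA from TC32 and TC71 cells was measured on 12 one-colour oligonucleotide arrays, 1 array per sample. The samples fall into 4 groups, TC32 and TC71 each with solvent control or mithramycin, with 3 arrays per group that the labels describe as biological replicates. The groups, the dose of 100 nM and the exposure of 6 h were taken from the labels.

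The deposited table holds 1 log2 value per probe set and array, and RMA (robust multi-array average) is named in the submitters' processing notes. The version of RMA, its settings and the probe set definition are not given in the sources used here. RMA corrects background, forces the same distribution of probe values on every array by quantile normalization and then summarizes the probes of a set on a log2 scale. A shift shared by most genes is therefore largely removed before deposition, and changes are relative to the other genes on the array. The summarized values did not share 1 distribution. Their interquartile range was lower with mithramycin, by -0.2 in TC32 and -0.132 in TC71, and their median was higher, by 0.049 and 0.039 (exact permutation p = 0.1 each, the smallest possible). The deposited log2 values had 0 missing cells. No detection calls, scan dates or batch labels were used here, so signal over background and batches could not be tested.

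Of the 54675 probe sets, 62 were control sets, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 were unnamed here. Older symbols were updated through Entrez gene identifiers in a RefSeq gene table for assembly GRCh38.p14, which matched 41037 probe sets. That table served only for names and to pass over genes of the Y chromosome. A comparison with gene length from that table was computed and then withdrawn, because no genome build is named for the arrays and the table was to serve for names only. In it longer genes tended to be lower with mithramycin in each line. The shifts of the Sp and KLF, histone, homologous recombination, IGF and PI3K, oxidative phosphorylation and interferon lists did not stand apart from random lists of genes of like length and signal, and the histone methylation list could not be decided. The EWS-FLI1 activated, G2/M, unfolded protein and TGF-beta lists did stand apart. The trend stayed with the beta-actin difference as a covariate. A test of lost 5' ends, written beforehand, set TC71 control replicate 1 against the other TC71 controls. Longer genes were lower on that array, which met the criterion set for such a loss. A loss in that control array would raise longer genes with mithramycin in TC71, opposite to the trend. The test rests on 1 array and says nothing about TC32 or the treated arrays, so lost 5' ends there stay undecided as a source of the trend. None of the other values rests on that comparison, so gene length stays an open influence on the falls, on the lists that did not stand apart and on the histone methylation list. Each of the 19775 genes tested was represented by the probe set with the highest mean over all arrays. Of the genes, 10523 had more than 1 probe set, and values of named genes are those of the brightest set. Where the sets of a named gene differed widely, the value of the set with the weakest or opposite change is given once beside them.

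All 12 arrays entered 1 linear model with a mean for each group, fitted with limma 3.58.1 in R 4.3.3 with empirical Bayes moderation. Values given for both lines are the mean of the TC32 and TC71 effects. Counts of calls given for both lines are those of that mean, as are counts of list members where no contrast is named. The contrasts were mithramycin minus control in TC32, the same in TC71, the mean of both effects, the difference of both effects (TC71 effect minus TC32 effect) and TC71 control minus TC32 control. Adjusted p-values are limma's, two-sided, with Benjamini-Hochberg adjustment over the genes of 1 contrast, and a gene was called at an adjusted p under 0.05. Errors of log2 fold changes are standard errors of the model. Genes that are compared across the lines are not independent replicates, so correlations across genes carry no p.

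The 29 gene lists were drawn up from textbook knowledge. They were EWS-FLI1 activated and repressed targets, Sp and KLF transcription factors, immediate early and short-lived mRNAs, p53 targets, histone genes, G1/S and replication, G2/M and mitosis, homologous recombination and Fanconi anaemia, BCL2 family and apoptosis inhibitors, unfolded protein and integrated stress response, heat shock, hypoxia and angiogenesis, cholesterol synthesis, cytosolic ribosomal proteins, oxidative phosphorylation, RNA polymerase II transcription and pausing, histone methylation, acetylation and Polycomb, MAPK feedback, IGF and PI3K signalling, TGF-beta and BMP early targets, Notch and Wnt targets, interferon response, housekeeping genes, and markers of neural, fibroblast, blood, epithelial and endothelial cells. Some genes stand on more than 1 list. Each list was tested against all other genes with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 29 lists of a contrast. The same test with an estimated correlation and the rotation test fry, which does not compare a list with other genes, were alternatives.

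Genes were named by a fixed rule. In TC32, in TC71, in both lines and between the controls these were the 10 highest and 10 lowest fold changes among genes that were called, had a mean of at least 6 in the higher group and showed no overlap between treated and control arrays. For the difference of the effects they were the 8 largest and 8 smallest differences among called genes with a mean of at least 6 in the highest group. Each list added the 4 members with the smallest adjusted p in both lines, and EWSR1, FLI1, NKX2-2, ID2, MYC, CCND1, EZH2, VEGFA, TGFBR2, IGFBP3, CDKN1A, MDM2, SP1 and SP3 were always examined. Genes known only by a clone or open reading frame name and genes of the Y chromosome were passed over.

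The lists, the naming rule, the model and the alternatives were chosen before the data were examined, except 2 alternatives named below. The alternatives were the mean of a gene's probe sets, every probe set tested, probe sets with the less specific _x_at and _s_at endings left out, only genes with a mean of at least 6, quantile normalization run again, centring on housekeeping genes or on the hybridization control sets, a trended robust prior, array weights, each line fitted alone, the replicate number as a block, an adjusted p under 0.01, a 2-fold change, and leaving out each array in turn. Centring on the array median and the beta-actin 3' minus 5' difference as a covariate were added after seeing the data.

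RNA quality was checked through the difference between the 3' and 5' control sets of beta-actin and GAPDH, with two-sided exact permutation tests per line, for which 3 arrays against 3 cannot give a p below 0.1. The model was tested on simulated data with the control means of each line and the gene variances of these arrays, in which 200 of the 19775 genes were changed. For the effect in TC32, it recovered 73.1% of genes changed by 0.5 log2 units and 100% of those changed by 1 unit, and 6.19% of its calls were unchanged genes. For the difference of the effects the shares were 46.3%, 88.1% for 1 unit, and 6.02% of the calls.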

Results

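Transcript levels were measured in TC32 and TC71, established human cell lines of Ewing sarcoma, a tumour in which the EWSR1-FLI1 fusion protein acts as an aberrant transcription factor. The cells received solvent or 100 nM mithramycin, an antibiotic that binds GC-rich DNA, for 6 h. Each of the 4 groups had 3 biological replicates with 1 array each, and this number limits the precision of every value. Over the probe sets, arrays of the same group correlated at 0.9948 or higher. Log2 fold changes are mithramycin minus control unless stated, given with the standard error of the model and n = 3 arrays per group.

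In TC32, the genes that fell furthest with mithramycin had varied roles. HDAC4, a class IIa histone deacetylase, fell by 3.43 ± 0.15 (adjusted p = 7.16e-09) and MAML2, a coactivator of Notch signalling, fell by 3.26 ± 0.12 (adjusted p = 1.86e-09). TET1, which oxidizes methylated cytosine, fell by 3.01 ± 0.07 and RFXAP, a subunit of the factor that drives MHC class II genes, fell by 3.21 ± 0.13. BCL11B, a zinc finger repressor, fell by 2.65 ± 0.06. The chemokine CXCL8 fell by 2.65 ± 0.14 and the guanine nucleotide exchange factor VAV2 fell by 2.73 ± 0.11. With mithramycin RFXAP, MAML2, TET1 and CXCL8 lay between 2.96 and 4.16, below the array medians of 4.38 to 4.47, so the sizes of their falls are rough. The highest increases were those of ALDH8A1, an aldehyde dehydrogenase, which rose by 3.82 ± 0.11 (adjusted p = 6.82e-10), and SCG5, a chaperone of neuroendocrine secretory granules, which rose by 3.65 ± 0.15. Their TC32 control arrays lay between 2.13 and 3.66, also below the array medians, so these sizes are rough too. The peptide genes LEAP2 and UCN rose by 2.28 ± 0.08 and 2.17 ± 0.16 and SLFN5 by 2.25 ± 0.09. The TC32 control arrays of UCN lay between 3.58 and 4.32, below the array medians, so the size of its rise is also rough. LSMEM1 rose by 2.24 ± 0.17, ZNF211 by 2.07 ± 0.06 and the antiproliferative gene TOB1 by 1.95 ± 0.08.

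Across the array, 5060 genes were called higher and 3831 lower in TC32, out of 19775 tested. Large changes ran mostly downward, with 670 genes at least 2-fold lower and 161 at least 2-fold higher, while the median change of all genes was 0.08. The probe sets of some genes disagreed. The weakest sets were at -0.86 for MAML2, -0.56 for TET1, -0.42 for RFXAP, -0.56 for BCL11B, 0.003 for VAV2, 0.92 for SLFN5 and 0.82 for LSMEM1. The 3 sets of HDAC4 ranged from -3.43 to -0.27, and the transcription factor gene EBF3 and SMAD6, an inhibitor of BMP signalling, which fell by 2.98 ± 0.07 and 2.76 ± 0.12 at their brightest sets, had others at -0.36 and 0.28. Higher genes made up 56.9% of the calls, against 46.3% with arrays centred on housekeeping genes and 11.7% (698 higher genes) with arrays centred on hybridization controls. Among genes with a mean of at least 6 the share was 49.5% (2966 higher and 3023 lower), and their median change was 0.013. The beta-actin 3' minus 5' difference, a sign of RNA integrity, was 0.60 ± 0.08 with mithramycin and 0.71 ± 0.04 in controls (SD, n = 3; exact permutation p = 0.2).

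In TC71, the genes that fell furthest also had varied roles. ATXN1, which encodes a transcriptional corepressor, fell by 3.49 ± 0.16 (adjusted p = 1.14e-08), KLHL29 fell by 3.33 ± 0.07 and the focal adhesion gene TNS1 fell by 3.10 ± 0.07. ZNRF3, a ubiquitin ligase that removes Wnt receptors from the cell surface, fell by 2.97 ± 0.09, and PAPPA, a protease that cleaves IGF-binding proteins, fell by 2.89 ± 0.11. EHMT1, a histone H3 lysine methyltransferase, fell by 2.85 ± 0.11, the teneurin gene TENM2 fell by 2.84 ± 0.07 and the homeobox gene ZFHX3 fell by 2.73 ± 0.08. The mithramycin arrays of ATXN1, TENM2 and ZFHX3 lay between 2.85 and 3.92, below the array medians, so the sizes of their falls are rough. SAT1, the acetyltransferase that starts polyamine breakdown, rose by 2.13 ± 0.07 (adjusted p = 1.69e-09). SCG5 rose by 1.77 ± 0.15, the matricellular gene CCN2 by 1.73 ± 0.07, and the B-cell survival factor TNFSF13B by 1.68 ± 0.08. TENT5C rose by 1.55 ± 0.14, TOB1 by 1.49 ± 0.08, OVGP1 by 1.45 ± 0.14 and the stress-induced factor ATF3 by 1.43 ± 0.10.

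The list of immediate early and short-lived mRNAs moved up in TC71, with 20 genes higher and 5 lower of 36 (20 and 6 adjusted over the list alone; median relative to all genes 0.18). Its camera adjusted p was 3.77e-03, against adjusted p = 0.112 with an estimated correlation, and the call ended without the _x_at and _s_at probe sets.

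In TC71 3828 genes were called higher and 3190 lower, with 90 and 492 of them at least 2-fold apart, and the median change of all genes was 0.07. The weakest probe sets were at 0.06 for KLHL29, -0.17 for TNS1, -0.495 for EHMT1, 0.14 for ZFHX3, 0.51 for TENT5C and 0.11 for ATF3. The 5 probe sets of ATXN1 ranged from -3.49 to 0.09, and 2 of the 11 sets of PAPPA were called in the opposite direction. EBF3 fell by 2.77 ± 0.07 at its brightest set while another of its 3 sets was called higher at 0.39. The beta-actin difference was 0.88 ± 0.10 with mithramycin and 1.45 ± 0.48 in controls (SD, n = 3; exact permutation p = 0.1, the smallest possible), and TC71 control replicate 1 stood at 2.0 against 1.08 and 1.28 in the other control arrays. With this difference as a covariate, chosen after seeing the data, 2158 genes were called higher and 2461 lower (46.7% higher). With arrays centred on housekeeping genes 1151 were higher, or 21% of the calls against 54.5%. Among genes with a mean of at least 6, 51.4% of the calls were higher, and the median change was 0.028.

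Among genes called in TC32 and also in TC71, most responded in the same direction. BCL11B fell by 2.62 in the mean of both lines, ATXN1 fell by 3.25 and ZNRF3 fell by 2.77, while ALDH8A1 rose by 3.34, SCG5 by 2.71, SAT1 by 2.02 and RSRP1 by 1.57 (adjusted p from 3.62e-12 to 1.47e-09). In each line ATXN1 with mithramycin and ALDH8A1 in controls lay below the array medians, so the sizes of their changes are rough. Among genes that were examined whatever their values, MYC fell by 0.84 ± 0.06 in TC32 and by 0.62 ± 0.06 in TC71, and VEGFA, the vascular growth factor, fell by 0.95 ± 0.07 and 0.70 ± 0.07, with 1 of its 4 probe sets at 0.05 in the mean of both lines. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 0.88 ± 0.06 and 0.48 ± 0.06. EWSR1 had a mean change of 0.02 (adjusted p = 0.742), with 2 of its 4 probe sets called lower and a range from -0.36 to 0.17. FLI1 fell by 0.48 (adjusted p = 1.49e-04), with 1 of its 6 sets called in the opposite direction. SP1 fell by 0.49 ± 0.06 in TC32 and 0.28 ± 0.06 in TC71, a call lost in TC71 with the mean of its probe sets (-0.16). SP3 fell by 0.24 in the mean of both lines at its brightest set, but the mean of its probe sets was 0.06. MDM2, the ubiquitin ligase of p53, fell by 0.38 in the mean of both lines, and the mean of its 10 probe sets was -0.002. EZH2 was at -0.11 (adjusted p = 0.047), a call lost in 10 of the 12 fits that each left out 1 array.

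**Figure D1:**
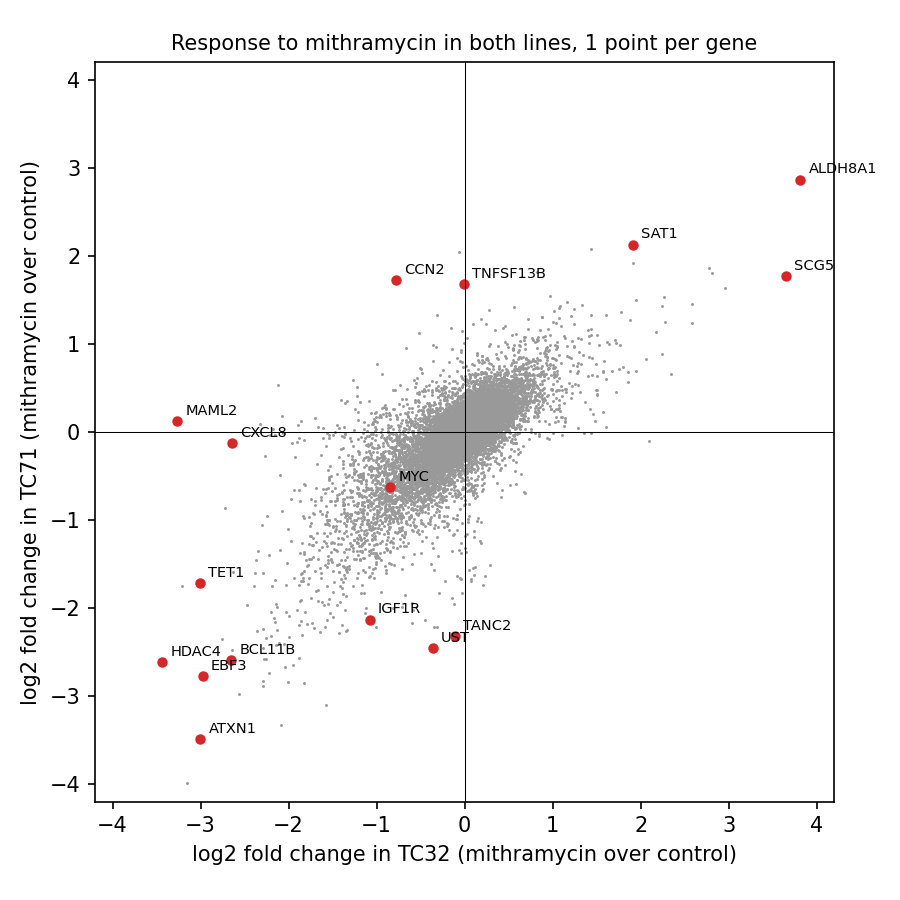
Log2 fold change of each gene in TC32 (x axis) and TC71 (y axis), mithramycin minus control, 1 point per gene, with 16 named genes in red. The points follow the diagonal (Pearson correlation 0.756), while MAML2 and CXCL8 lie low in TC32 only and TANC2 and UST low in TC71.

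In the mean of both lines 6500 genes were called higher and 4131 lower, with 91 and 500 at least 2-fold apart. The fold changes correlated at 0.756 (Pearson) and 0.676 (Spearman) across genes, and at 0.835 (Pearson) over the 8386 genes with a mean of at least 6. Of the genes called higher in TC32, 2581 were also called higher in TC71, where independent lists would share 979.5, and 2512 were called lower in each line against 618. Among genes called in TC32 and also in TC71, 96.9% had the same direction. Higher genes made up 61.1% of the calls in both lines, 37.0% with centring on housekeeping genes and 34.9% with centring on hybridization controls. Among genes with a mean of at least 6 the share was 51.6% (3335 higher and 3124 lower). Their median change was 0.021, against 0.077 for all genes, so the excess of rises lay mostly in dimmer genes.

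The 43 measured EWS-FLI1 activated targets, genes that the fusion protein is known to switch on, moved down as a list. In the mean of both lines 29 fell and 4 rose (29 and 5 adjusted over the list alone). The list's median lay -0.31 from that of all genes (camera adjusted p = 1.12e-08, and adjusted p = 0.0691 with an estimated correlation). By line, 23 fell and 4 rose in TC32, and 26 fell and 6 rose in TC71. Members that fell in both lines included BCL11B, PAPPA, SOX6, a transcription factor of skeletal development, which fell by 1.67 ± 0.06 and 1.79 ± 0.06 with 1 of its 8 probe sets called in the opposite direction, and CCND1, the G1 cyclin D1, which fell by 0.23 ± 0.06 in TC32 and 0.95 ± 0.06 in TC71. JARID2 fell by 1.68 in both lines at its brightest set, and without the _x_at and _s_at sets its change was -0.06. The homeobox gene NKX2-2 fell by 0.64 ± 0.06 in TC32 and stood at 0.17 ± 0.06 in TC71 (adjusted p = 0.0395), a call lost in 8 of the 12 fits that each left out 1 array. ID2, an inhibitor of helix-loop-helix factors, fell by 0.28 in TC32 and rose by 0.43 in TC71.

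Lists of chromatin and growth factor genes also moved down. Gene length stays an open influence on the histone methylation, IGF and PI3K, and Sp and KLF lists among them. Of 31 genes of histone methylation, acetylation and Polycomb, 21 fell and 3 rose in the mean of both lines (21 and 3 adjusted over the list alone). The list's median relative to all genes was -0.34 (camera adjusted p = 8.98e-07, adjusted p = 0.0963 with an estimated correlation). By line, 18 fell and 2 rose in TC32, and 16 fell and 2 rose in TC71. Those that fell included EHMT1, HDAC4 and the acetyltransferase gene CREBBP, which fell by 2.05 with 1 of its 4 probe sets called in the opposite direction. Of 21 IGF and PI3K signalling genes, 13 fell and 3 rose (the same numbers adjusted over the list alone; -0.34; camera adjusted p = 2.26e-04, adjusted p = 0.12 with an estimated correlation). The receptor gene IGF1R fell by 1.08 ± 0.08 in TC32 and 2.13 ± 0.08 in TC71, with 5 probe sets between -1.83 and 0.18 in both lines. IRS2, an adaptor of insulin and IGF receptors, fell by 0.92 and 0.70, and FOXO1 by 1.33 and 0.92, with its weakest probe set at 0.145 in the mean of both lines. Of 19 TGF-beta and BMP early targets, 11 fell and 5 rose (the same adjusted over the list alone; -0.51; camera adjusted p = 1.63e-03, adjusted p = 0.12 with an estimated correlation), including SKI, a repressor of SMAD signalling, which fell by 1.66 with 1 of its 3 probe sets called in the opposite direction, and PMEPA1, which fell by 1.41 (weakest set -0.47). SMAD6 fell by 2.56 at its brightest set and was at 0.21 without the _x_at and _s_at sets. Of 17 Sp and KLF transcription factor genes, 10 fell and 3 rose in the mean of both lines (the same adjusted over the list alone; -0.25; camera adjusted p = 0.0186, adjusted p = 0.252 with an estimated correlation). By line, 11 fell and 2 rose in TC32 (camera adjusted p = 6.28e-03). In TC71 5 fell and 3 rose, and the list was not called (camera adjusted p = 0.135). For the difference of the effects the list was not called either (camera adjusted p = 0.155, adjusted p = 0.547 with an estimated correlation). The counts by line therefore do not show that the lines differed for this list. KLF12 fell by 1.13 (weakest set 0.09) and SP2 by 0.52 (weakest set -0.03), whereas KLF13 fell by 0.88 at its brightest set and was at 0.07 without the _x_at and _s_at sets. The call of the Sp and KLF list ended with the mean of probe sets, with a mean of at least 6 and with quantile normalization run again.

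Genes of mitosis, DNA repair and the stress response of the endoplasmic reticulum formed a further group, in which gene length stays an open influence on the homologous recombination list. Of 29 G2/M and mitosis genes, 16 fell and 3 rose in the mean of both lines (the same adjusted over the list alone; -0.26; camera adjusted p = 7.66e-04, adjusted p = 0.136 with an estimated correlation). By line, 19 fell and 3 rose in TC32 (camera adjusted p = 3.35e-05). In TC71 9 fell and 3 rose, and the list was not called (camera adjusted p = 0.0873). The spindle checkpoint kinase BUB1B fell by 0.80 ± 0.05 in TC32 and 0.79 ± 0.05 in TC71, and the spindle motor KIF11 by 1.02 ± 0.08 and 0.69 ± 0.08. Of 19 genes of homologous recombination and the Fanconi anaemia pathway, 11 fell and 1 rose (the same adjusted over the list alone; -0.25; camera adjusted p = 3.26e-04, adjusted p = 0.0685 with an estimated correlation). The helicase gene BLM fell by 0.91 in each line, BRIP1 by 0.51 and 0.86, and BARD1, the partner of BRCA1, by 1.18 and 0.51. Of 23 genes of the unfolded protein and integrated stress response, 15 fell and 4 rose (15 and 5 adjusted over the list alone; -0.45; camera adjusted p = 2.82e-04, adjusted p = 0.143 with an estimated correlation). ATF4, the main transcription factor of the integrated stress response, fell by 1.09 ± 0.05 and 0.65 ± 0.05 and CEBPB by 1.01 ± 0.05 and 0.34 ± 0.05, while ATF3 on the same list rose by 1.09 ± 0.10 and 1.43 ± 0.10.

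Histone, interferon response and oxidative phosphorylation genes moved up, and gene length stays an open influence on each of these lists. Of 12 histone genes, 8 rose and 1 fell in the mean of both lines (the same adjusted over the list alone). Their median was 0.17 relative to all genes (camera adjusted p = 0.0186, adjusted p = 0.12 with an estimated correlation). By line, 7 rose in TC32 and 6 in TC71, and 0 fell in each. H2BC21 rose by 1.17 ± 0.10 in TC32 and 1.48 ± 0.10 in TC71, and H2BC4 by 0.60 ± 0.10 and 0.83 ± 0.10. On the TC32 control arrays H2BC21 lay between 3.32 and 3.61 and H2BC4 between 3.93 and 4.21. These levels are below the array medians, so the sizes of their rises in TC32 are rough. Without the _x_at and _s_at probe sets the median of the histone genes lay at -0.009 relative to all genes and the call ended. Of 20 interferon response genes, 11 rose and 2 fell (the same adjusted over the list alone; 0.13; camera adjusted p = 0.0352, adjusted p = 0.12 with an estimated correlation), among them IFI6 by 0.71 ± 0.05 and 0.55 ± 0.05, the ubiquitin-like modifier ISG15 by 0.76 ± 0.06 and 0.48 ± 0.06, and IRF1 by 0.60 ± 0.08 and 0.72 ± 0.08. Of 24 nuclear-encoded genes of oxidative phosphorylation, 19 rose and 0 fell in the mean of both lines (the same adjusted over the list alone). Their median was 0.06 relative to all genes (camera adjusted p = 2.35e-03, adjusted p = 0.22 with an estimated correlation). By line, 15 rose in TC32 but only 7 in TC71, and 0 fell in each. The rises were small, such as 0.23 for the complex I gene NDUFS3 and 0.24 for the complex III gene UQCRC1. Relative to all genes, the median of the oxidative phosphorylation list in the mean of both lines stayed at 0.058 under both centrings and between 0.045 and 0.113 over the alternatives, although its call in both lines ended with each centring. Its median before that subtraction was -0.07 in TC32 with centring on hybridization controls and -0.04 in TC71 with centring on housekeeping genes, because a centring shifts every gene of an array alike. The median change of all genes was then -0.14 in TC32 and 0.14 in TC71 (hybridization controls) and -0.07 in TC71 (housekeeping genes). Restricted to genes with a mean of at least 6, the calls of the EWS-FLI1 activated, histone methylation and oxidative phosphorylation lists stood and the other 8 ended.

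**Figure D2:**
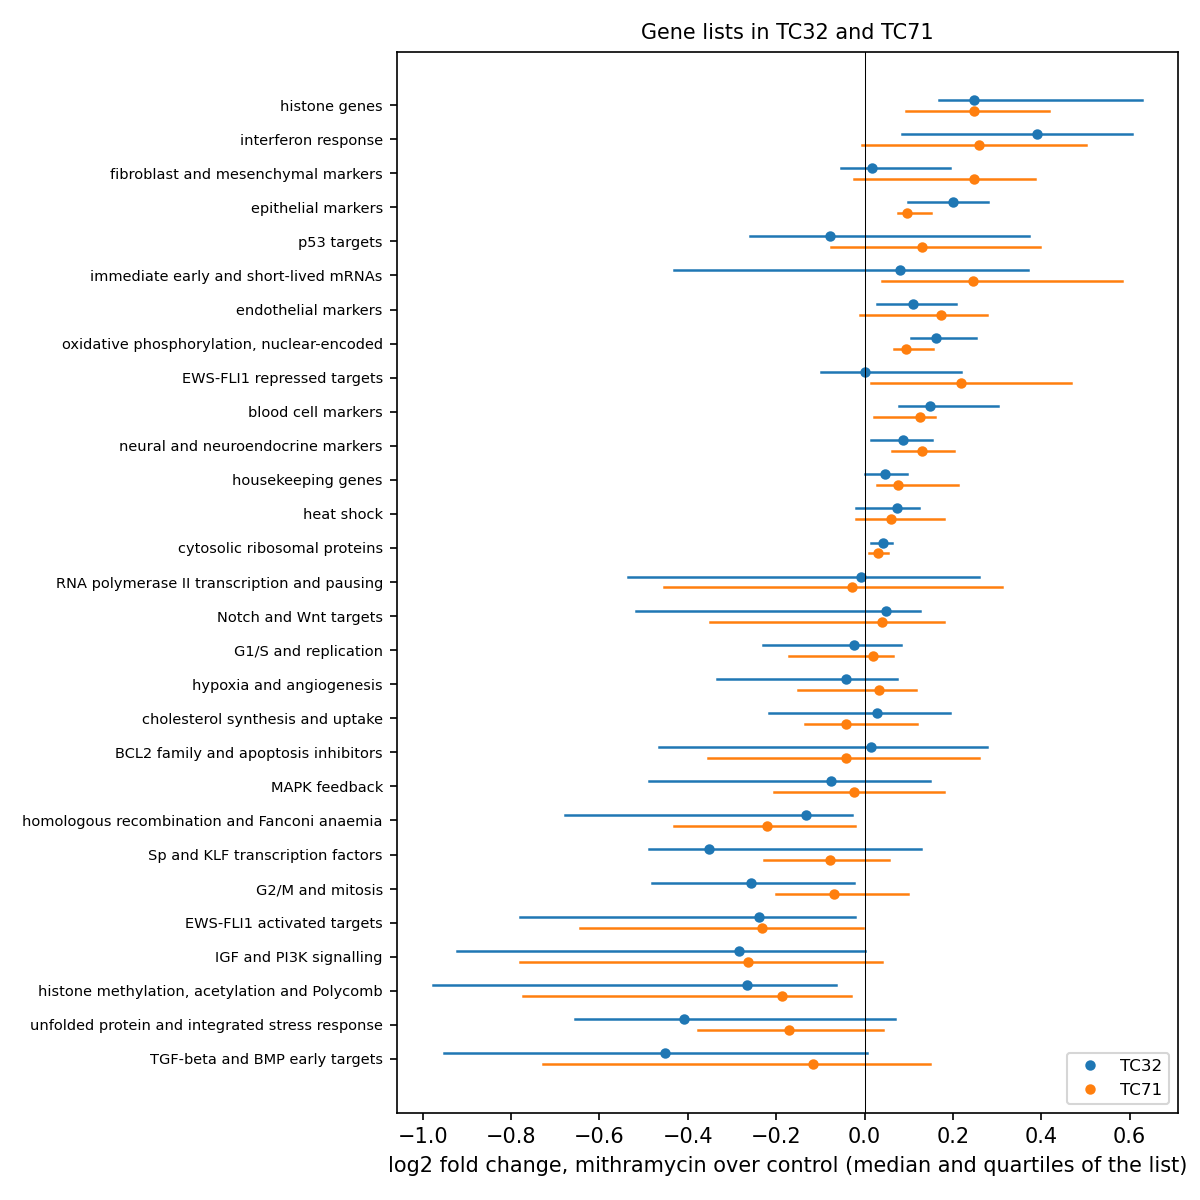
Log2 fold change (mithramycin minus control) of the 29 gene lists in TC32 (blue) and TC71 (orange), with the median as a point and the quartiles over the genes of a list as a line. The EWS-FLI1 activated targets lie at medians of -0.24 and -0.23, and values include the shift shared by all genes, which centring on control sets moves: the oxidative phosphorylation median then reads -0.07 in TC32 (hybridization controls) and -0.04 in TC71 (housekeeping genes), and lies at 0.078 in TC32 and 0.028 in TC71 relative to all genes.

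The other 18 lists were not called in the mean of both lines. In 12 of them some genes rose and others fell. These were 18 and 10 of 36 immediate early and short-lived mRNAs, 11 and 8 of 23 p53 targets, 12 and 4 of 23 EWS-FLI1 repressed targets (12 and 5 adjusted over the list alone). Higher and lower were 14 and 15 of 34 RNA polymerase II genes, 7 and 7 of 18 BCL2 family genes, 4 and 7 of 20 hypoxia genes. They were 4 and 8 of 19 MAPK feedback genes, 4 and 8 of 20 Notch and Wnt targets (4 and 9 over the list alone), 3 and 8 of 27 G1/S genes (3 and 7). They were 4 and 4 of 14 cholesterol genes, 2 and 1 of 12 heat shock genes and 4 and 1 of 12 housekeeping genes. None of the 19 cytosolic ribosomal protein genes was called by limma in both lines. Of the cell type markers, 3 of 15 neural (1 adjusted over the list alone), 8 of 16 fibroblast, 2 of 11 blood, 4 of 14 epithelial and 5 of 14 endothelial genes rose and 0 fell. Where not stated, the numbers adjusted over the list alone were the same. For comparison, 6500 of all 19775 genes were called higher. Several markers, among them COL1A2, KRT19, GRHL2 and VWF, lay below the array medians on every array, so these counts do not show that markers of a cell type were induced. Camera's adjusted p ranged from 0.124 for the G1/S list to 0.562 for the heat shock list.

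Single genes of these lists changed strongly all the same. PFKFB3, which sets the rate of glycolysis, fell by 2.15 ± 0.06 in TC32 and 1.68 ± 0.06 in TC71, the receptor gene NOTCH1 fell by 1.16 ± 0.15 and 1.29 ± 0.15, and NRARP, a feedback inhibitor of Notch, rose by 1.05 ± 0.07 and 0.97 ± 0.07. Of the apoptosis regulators, the inhibitors BCL2 and BCL2L2 fell by 1.45 ± 0.10 and 1.51 ± 0.05 in TC32 and by 1.51 ± 0.10 and 0.58 ± 0.05 in TC71, and the proapoptotic PMAIP1 rose by 0.97 ± 0.05 and 0.99 ± 0.05. The mean of the probe sets of BCL2 was -0.405 in both lines, and the weakest sets were at -0.09 for BCL2L2 and 0.07 for NOTCH1. MLLT1 and AFF1, parts of complexes that aid elongation by RNA polymerase II, fell by 1.08 and 0.998 in the mean of both lines, but other sets were at 0.12 for each, and the mean of the probe sets of AFF1 was -0.284. HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose by 1.07 at its brightest set and was at 0.003 without the _x_at and _s_at sets. The p53 targets DDB2 and XPC, both of nucleotide excision repair, rose by 0.57 and 0.66 in TC32 and by 0.38 and 0.25 in TC71.

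**Figure D3:**
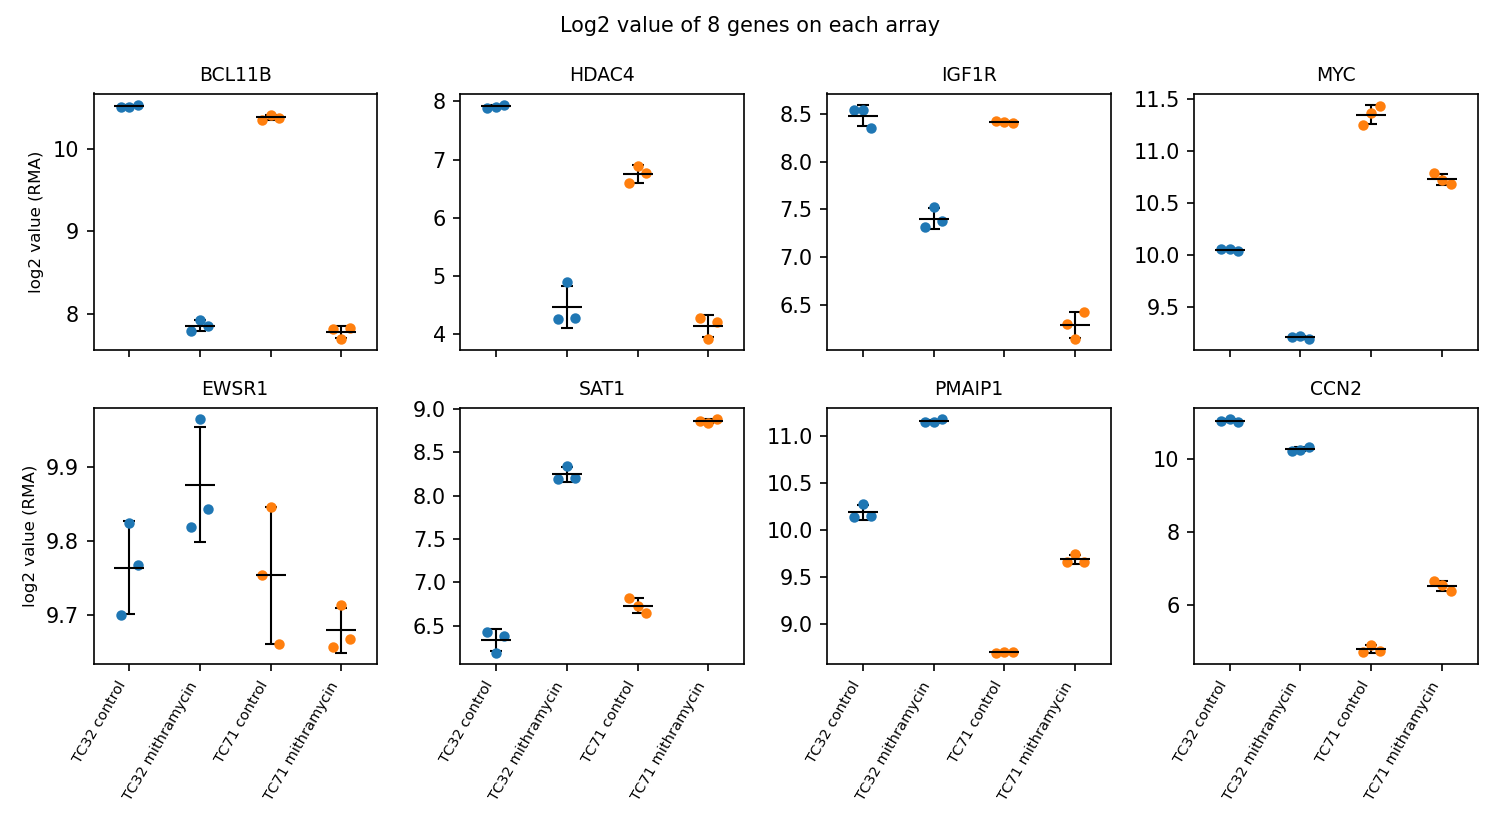
Log2 value on each array for 8 genes in the 4 groups (x axis), with points for single arrays and bars for the mean and SD of 3 arrays, on y axes that differ between panels and do not start at 0. BCL11B, HDAC4, IGF1R and MYC lie lower and SAT1 and PMAIP1 higher on all mithramycin arrays of each line, while CCN2 goes down in TC32 and up in TC71.

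The difference of the effects asks where the lines responded unequally. MAML2 fell by 3.26 ± 0.12 in TC32 and was at 0.12 ± 0.12 in TC71, a difference of 3.38 ± 0.17 (adjusted p = 1.45e-06), and CXCL8 fell by 2.65 in TC32 and was at -0.12 in TC71, a difference of 2.52 ± 0.20. CCN2 fell by 0.78 ± 0.07 in TC32 and rose by 1.73 ± 0.07 in TC71 (difference 2.51 ± 0.10; adjusted p = 4.55e-07). In the other direction, TANC2 was at -0.11 ± 0.12 in TC32 and fell by 2.32 ± 0.12 in TC71 (difference -2.21 ± 0.17; adjusted p = 1.33e-05), and TGFA, a ligand of the EGF receptor, was at 0.21 ± 0.12 and fell by 1.74 ± 0.13 (difference -1.96 ± 0.18). SCG5 rose in both lines, by 1.88 ± 0.22 less in TC71 (difference -1.88). In TC71, MAML2 and CXCL8 lay between 2.41 and 3.10 on every array, and TGFA in TC32 between 2.73 and 3.34. These levels are below the array medians of 4.38 to 4.47, so a fall may have been hidden there and such differences compare a response with a gene at low signal. How far such signals stand above background is unknown. Probe sets also disagreed, with the smallest differences at 0.90 for MAML2, -0.19 for TANC2 and -0.165 for TGFA. All 8 genes with the highest differences were lower in TC71 controls than in TC32 controls, by log2 differences from -8.37 for SOX1 to -3.48 for GBGT1, and all 8 with the lowest were higher, from 2.13 for SCG5 to 4.78 for ZFPM2.

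The list of immediate early and short-lived mRNAs had the clearest difference, with 17 of 36 genes higher and 1 lower in their response in TC71 (19 and 2 adjusted over the list alone; median relative to all genes 0.35; camera adjusted p = 1.09e-08, adjusted p = 0.0276 with an estimated correlation). IER3 rose by 0.34 ± 0.05 in TC32 and 1.16 ± 0.05 in TC71 and IER5 by 0.54 ± 0.06 and 1.11 ± 0.06. EWS-FLI1 repressed targets differed too, with 9 of 23 higher and 1 lower (10 and 2 adjusted over the list alone; 0.25; camera adjusted p = 1.26e-03, adjusted p = 0.042 with an estimated correlation). With only genes of a mean of at least 6, the call of the EWS-FLI1 repressed targets ended (adjusted p = 0.312), and that of the immediate early and short-lived mRNAs stood (adjusted p = 3.59e-05). TGFBR2 fell by 1.21 ± 0.09 in TC32 and 0.36 ± 0.09 in TC71, with its other probe set at 0.01 in the mean of both lines. IGFBP3 fell by 1.02 ± 0.15 in TC32 and was at 0.22 ± 0.15 in TC71. There it lay between 2.92 and 3.74 on all arrays, below the array medians, where a fall may not show. The G2/M genes had 8 of 29 higher and 0 lower (11 and 0 adjusted over the list alone; 0.15; camera adjusted p = 4.72e-06, adjusted p = 0.0946 with an estimated correlation), among them AURKA, a mitotic kinase, which fell by 0.80 ± 0.05 and 0.38 ± 0.05.

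In total 1239 genes had a higher and 736 a lower response in TC71 than in TC32, and 1126 of these 1975 had a control mean of at least 6 in both lines. Higher responses made up 62.7% of the calls, 39.4% with centring on housekeeping genes and 95.2% with centring on hybridization controls (2975 higher and 150 lower). With the beta-actin difference as a covariate, chosen after seeing the data, 796 were higher and 409 lower. By array, that difference lay between 0.51 and 0.74 in TC32 and between 0.79 and 2.0 in TC71.

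Without the drug the lines differed by more than mithramycin changed either of them. Relative to TC32, TC71 controls were higher for UTS2, the precursor of urotensin 2, by 8.82 (adjusted p = 8.77e-12), for CTCFL, the testis paralogue of CTCF, by 7.81, for the piRNA methyltransferase HENMT1 by 7.33 and for the neurofilament gene NEFH by 6.96. They were lower for the homeobox gene OTX2 at -8.89 (adjusted p = 7.22e-15), SOX1 at -8.37 and the chemokine CXCL14 at -9.06. They were also lower for the chemokine receptor ACKR3 at -7.65, the matrix genes TGFBI and TNC at -7.44 and -6.69, and the T-box factor TBX5 at -6.84 (n = 3 each). Other probe sets gave differences closer to 0, among them -2.37 for CXCL14, -0.37 for ACKR3, -0.555 for SOX1, -2.86 for TBX5, -3.59 for TNC and 2.18 for UTS2. Except for TNC, these genes lay between 1.77 (OTX2) and 4.19 (NEFH) on the control arrays of the lower line, below the array medians. The sizes of these differences, those of UTS2, CTCFL and OTX2 included, are therefore rough. Of 23 EWS-FLI1 repressed targets, 15 were lower and 4 higher in TC71 (the same adjusted over the list alone; median relative to all genes -0.86; camera adjusted p = 4.73e-04, adjusted p = 0.0247 with an estimated correlation), and of 19 MAPK feedback genes 14 were lower and 2 higher (the same over the list alone; -0.61; camera adjusted p = 6.85e-04, adjusted p = 0.0247 with an estimated correlation). The unfolded protein and integrated stress response had 17 of 23 genes lower and 6 higher (the same over the list alone; -0.40; camera adjusted p = 0.0393, adjusted p = 0.528 with an estimated correlation). Histone genes were higher, 11 of 12 against 1 lower (the same over the list alone; 1.13; camera adjusted p = 3.98e-04, adjusted p = 0.0247 with an estimated correlation).

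Between the controls 5281 genes were called higher and 4904 lower in TC71, 1537 and 1117 of them at least 2-fold apart. Higher genes were 51.9% of the calls, 79.4% with centring on housekeeping genes, which moved the median difference of all genes to 0.24, and 41.4% with centring on the array median, chosen after seeing the data. The beta-actin 3' minus 5' difference was 1.45 ± 0.48 in TC71 controls and 0.71 ± 0.04 in TC32 controls (SD, n = 3).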

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

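The tests of low signal, of RNA quality, of mRNA lifetime and of the ribosomal control set were chosen only after the results were seen, and the splits of the arrays were planned.

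The lines differed in their response to mithramycin by a test of the difference itself: 1239 genes had a higher and 736 a lower response in TC71 than in TC32. The balance depends on the scaling, with 644 higher and 991 lower when arrays are centred on housekeeping genes and 2975 higher and 150 lower when they are centred on hybridization controls. Gene lists differed as well, with median differences (TC71 effect minus TC32 effect) of 0.227 for EWS-FLI1 repressed targets (adjusted p = 0.042 with an estimated correlation), 0.331 for immediate early and short-lived mRNAs (adjusted p = 0.0276 with an estimated correlation), 0.133 for G2/M and mitosis (adjusted p = 0.0946 with an estimated correlation), 0.107 for the unfolded protein and integrated stress response (adjusted p = 0.415 with an estimated correlation), 0.163 for hypoxia and angiogenesis (adjusted p = 0.27 with an estimated correlation) and 0.174 for TGF-beta and BMP early targets (adjusted p = 0.366 with an estimated correlation). The call of the hypoxia list was lost without TC32 mithramycin replicate 1 and without TC71 mithramycin replicate 1, and that of the TGF-beta list without TC32 mithramycin replicate 1, TC32 control replicate 2 or TC71 mithramycin replicate 3. The genes with the highest differences were MAML2 at 3.382, GBGT1 at 2.663, CXCL8 at 2.524, CCN2 at 2.511, SFMBT2 at 2.419, ZNF521 at 2.257, SOX1 at 2.218 and PDE7B at 2.122. Those with the lowest were TANC2 at -2.213, UST at -2.094, TGFA at -1.958, KCNQ5 at -1.905, SCG5 at -1.882, AHRR at -1.869, ZFPM2 at -1.868 and CUX2 at -1.799. MAML2, GBGT1, CXCL8, SFMBT2, ZNF521 and SOX1 lay below the array medians on every TC71 array. The same held for UST, TGFA, KCNQ5, AHRR, ZFPM2 and CUX2 on every TC32 array, so these sizes are rough.

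Low signal in the controls of 1 line could hide a response there. A control mean of at least 6 in both lines was found for 57.01% of the called differences and for 7759 of the 19775 genes tested. Low control signal thus cannot be the whole source of the calls. None of the genes named above for the highest and lowest differences passed this filter. Each had a control mean under 6 in 1 line, so low signal stays open for them. The filter covers controls only, so a gene that fell below 6 with mithramycin could still pass it. HDAC4, for instance, lay between 6.59 and 7.93 on the control arrays and between 3.93 and 4.89 with mithramycin. Low signal after treatment was not tested and stays open as a source of the calls. The RNA of TC71 control replicate 1, whose beta-actin 3' minus 5' difference was the highest, is another candidate source, yet 72.15% of the calls, 1425 of 1975, stayed in the same direction without that array. This speaks only to that array. The other TC71 controls (1.08 and 1.28) also lay above every TC71 mithramycin array (0.79 to 0.99). With the beta-actin difference as a covariate, 796 genes were called higher and 409 lower, so RNA quality stays open for part of the calls. By splits of the arrays alone chance cannot be excluded for the number of calls, since 8 of 100 splits, the real one included, called at least 1975 genes, and the highest other split called 10631. Splits that call several times the real number show a structure of the samples, because exchanging treated and control arrays in 1 line turns the shared effect of mithramycin into a difference between the lines, so the splits decide nothing about this count. Of the called differences, 163 were in genes called in opposite directions in TC32 and TC71, such as CCN2, whose call stood in all 12 fits that each left out 1 array. The contrast itself was planned. That its calls reflect the biology of the cell lines remains a hypothesis, since the tests of technical sources ran on the same arrays.

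The 3' set of the 18S ribosomal RNA controls, which is outside the gene comparisons, rose by 1.195 in TC32 and 1.338 in TC71 with mithramycin. More ribosomal RNA in the labelled material is argued against by the other 18S sets, whose changes were at most 0.128, and array scaling by the hybridization controls, whose higher change was 0.229 (TC32). Loss of 5' ends with mithramycin would raise the beta-actin 3' minus 5' difference, which was lower, by -0.11 in TC32 and -0.573 in TC71. In TC71 every mithramycin array (0.79 to 0.99) lay below every control (1.08 to 2.0), which argues against such a loss there. In TC32 the arrays overlapped (exact permutation p = 0.2), so the test over both lines stayed undecided. The GAPDH difference hardly moved in either line. No biological explanation was tested.

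Among the probe sets unnamed here, which no gene comparison used, 132 were at least 2-fold higher with mithramycin in the mean of both lines. At least 2-fold lower in that mean were 154.

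For the effect of mithramycin in both lines, chance is an unlikely source of the number of calls: 1 of 100 splits, the real one, gave the 10631 calls, and the highest other split gave 3084. A share of 1 in 100 is the smallest that these splits can give, so they do not exclude chance. A batch that runs with the treatment would give the same result and could not be tested. Within a line 10 splits exist, too few for a share under 0.05. The real value and the highest other were 8891 and 1 genes in TC32, 7018 and 0 in TC71, and 10185 and 0 between the controls.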

How the results depend on the processing

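The covariate and the centring on the array median were chosen only after the results were seen. Leaving out each of the 12 arrays in turn kept each count of genes, and the overlap of calls between the lines, within 1.5 times its value and the calls of all 11 lists called in both lines, and the correlation of the lines stayed between 0.744 and 0.758, its lowest value without TC71 mithramycin replicate 2. Over those fits 6200 results for single genes were the same, 122 lost and 38 gained a call. Over the other alternatives 5617 were the same, 179 lost and 87 gained a call, and 35 reversed. In TC71 alone the list of EWS-FLI1 repressed targets was called at 0.0499, a call lost in 9 of the 12 fits. No detection calls were used, so how far dim genes stand above background is unknown. List values below are medians relative to all genes, and where no reason is given the cause was not tested.

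With the mean of a gene's probe sets, the correlation of the lines was 0.731 and the Sp and KLF transcription factors lost their call at -0.16. The signs of POLH (both) 0.008, DNAJB1 (both) 0.048, DLG4 (both) -0.135, EWSR1 (both) -0.101, SP3 (both) 0.06, POLH (TC32) 0.114, RPS15 (TC32) -0.188, DLG4 (TC71) -0.164 and SP3 (TC71) 0.14 reversed. Without the _x_at and _s_at sets, the correlation was 0.743, histone genes lost their call at -0.009. The signs of SMAD6 (TC32) 0.28, EBF3 (TC71) 0.394, TANC1 (TC71) 0.105, EBF3 (both) 0.018, SMAD6 (both) 0.212, KLF13 (both) 0.071, CFLAR (both) 0.159, DLG4 (both) -0.494, LUM (both) -0.012, EWSR1 (both) -0.356, JARID2 (TC32) 0.016, KLF13 (TC32) 0.071, CFLAR (TC32) 0.012, RPS15 (TC32) -0.432, HEXIM1 (TC32) -0.037, DLG4 (TC32) -0.447, EWSR1 (TC32) -0.56, SMAD6 (TC71) 0.143, CXCL14 (TC71) -0.003, KLF13 (TC71) 0.072, CFLAR (TC71) 0.306, DLG4 (TC71) -0.541 and LUM (TC71) -0.08 reversed, since another probe set then stands for the gene. With every probe set tested, which tests more features, calls were 8516 higher and 7697 lower in TC32, 6435 and 6348 in TC71, 11429 and 8613 in both lines, 2005 and 1120 for the difference of the effects, 9610 and 9669 between the controls, and 9086 were shared by the lines.

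With genes of a mean of at least 6, fewer genes were tested: 2966 were higher and 3023 lower in TC32, and 3335 and 3124 in both lines. The share of higher genes was then 49.5% in TC32 and 51.6% in both lines. Between the controls 3178 were lower, and the correlation was 0.835. With this filter 3 lists stayed called, and calls ended for Sp and KLF transcription factors -0.266, histone genes 0.211, G2/M and mitosis -0.202, homologous recombination and Fanconi anaemia -0.191, unfolded protein and integrated stress response -0.302, IGF and PI3K signalling -0.283, TGF-beta and BMP early targets -0.249 and interferon response 0.403. Quantile normalization run again ended the call of the Sp and KLF transcription factors at -0.217. Centring on housekeeping genes gave 3298 higher genes in TC32, 1151 in TC71, 2949 in both lines, 644 for the difference of the effects, and 9899 higher and 2562 lower between the controls. Centring on hybridization controls gave 698 higher in TC32, 1983 lower in TC71, and 2212 higher in both lines. It gave 2975 higher and 150 lower for the difference of the effects, 3165 lower between the controls, and an overlap of calls between the lines of 2407. The signs of HSPB1 (TC32) -0.008, BAG3 (TC32) -0.018 and IDI1 (TC32) -0.004 reversed. Both centrings ended the call of oxidative phosphorylation, at 0.058. They add the spread of a few sets to every gene.

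At an adjusted p under 0.01, 3118 genes were higher in TC32, 2272 in TC71, and 670 and 306 for the difference of the effects. At 2-fold or more, calls were 161 higher and 670 lower in TC32, 90 and 492 in TC71, 91 and 500 in both lines, 153 and 103 for the difference of the effects, 1537 and 1117 between the controls, with 366 shared. With the beta-actin covariate, TC71 had 2158 higher and 2461 lower genes, and the difference of the effects 796 higher and 409 lower.

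With an estimated correlation, camera called 0 of the 29 lists in both lines. The calls lost were EWS-FLI1 activated targets -0.313, Sp and KLF transcription factors -0.253, histone genes 0.17, G2/M and mitosis -0.258, homologous recombination and Fanconi anaemia -0.247, unfolded protein and integrated stress response -0.446, oxidative phosphorylation, nuclear-encoded 0.058, histone methylation, acetylation and Polycomb -0.338, IGF and PI3K signalling -0.338, TGF-beta and BMP early targets -0.514 and interferon response 0.133. Fry, which tests a list's own change against 0 and not against all genes, called all 29. With medians still relative to all genes, it added EWS-FLI1 repressed targets 0.039, immediate early and short-lived mRNAs 0.076, p53 targets 0.081, G1/S and replication -0.072, BCL2 family and apoptosis inhibitors -0.111, heat shock -0.028, hypoxia and angiogenesis -0.08, cholesterol synthesis and uptake -0.095, cytosolic ribosomal proteins -0.035, RNA polymerase II transcription and pausing -0.06, MAPK feedback -0.166, Notch and Wnt targets -0.062, housekeeping genes -0.017, neural and neuroendocrine markers -0.015, fibroblast and mesenchymal markers 0.095, blood cell markers 0.036, epithelial markers 0.084 and endothelial markers 0.064. The direction by fry was up for heat shock, cytosolic ribosomal proteins, housekeeping genes and neural markers, whose medians are above 0 before the median of all genes is subtracted. In TC32 fry put p53 targets (-0.162) in the opposite direction to camera.

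The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at 0.082, 0.236 and 0.04 in TC32 and -0.071, -0.019 and -0.012 in TC71, and not every array correlated best with its own number. With the replicate number as a block, calls were 4998 higher and 3749 lower in TC32, 3689 and 3111 in TC71, 6465 and 4118 in both lines, 981 and 591 for the difference of the effects, 5275 and 4890 between the controls, each within 1.5 times its value. The block ended the calls of EWS-FLI1 repressed targets and interferon response in TC71.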

Other observations

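The members named in the next paragraph were picked after their values were seen, and the tests of the falls and rises were chosen only after the result was seen.

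Within the list of immediate early and short-lived mRNAs, some members responded differently in the lines. FOS, a member of the AP-1 family, fell by 0.998 in TC32 (adjusted p = 5.99e-07) and rose by 0.77 in TC71 (adjusted p = 7.57e-06), a difference of 1.77 (limma adjusted p = 4.61e-06). FOSL2 fell by 1.01 in TC32 and was at 0.01 in TC71 (difference 1.03), and EGR1, a zinc finger factor induced by growth signals, fell by 0.47 in TC32 and rose by 0.46 in TC71 (difference 0.94). BTG1 and NFKBIZ rose in both lines, by 0.24 and 0.72 in TC32 and by 1.22 and 1.29 in TC71. Between lists, CCN1 was at -0.04 in TC32 and rose by 1.15 in TC71, beside its relative CCN2.

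The 28S ribosomal RNA control sets differed between the lines in their values. In TC71 the middle set was 8.89 ± 0.19 with mithramycin and 9.73 ± 0.13 in controls (SD, n = 3; exact permutation p = 0.1, the smallest possible), and in TC32 it was 10.5 ± 0.17 and 10.5 ± 0.14. Its difference of the effects was -0.889 (limma p adjusted over all probe sets = 5.32e-03). The change of the 5' set in TC71 was -0.434 (adjusted p = 1.76e-03 by the same test), and that of the 3' set was 0.169 (adjusted p = 0.242).

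Falls of at least 2-fold outnumbered such rises, 500 to 91 in the mean of both lines. Low signal could bias such counts, but 88.51% of the 383 genes called at least 2-fold with a mean of at least 6 fell. A general loss of short-lived mRNA, as a hypothesis, would lower the immediate early and short-lived list unless new transcription offset it. The median change of that list was 0.152 (interquartile range 0.638), against -1.269 for the genes called at least 2-fold lower. By line, 13 of its 36 genes were called higher and 15 lower in TC32, and 20 and 5 in TC71. The list thus did not fall as a whole. Lifetimes were not measured apart from transcription, so loss of short-lived mRNA stays undecided. Selective effects on particular genes stay open. Gene length is among them, since longer genes tended to be lower in a comparison that was withdrawn for want of a named genome build.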
